A study of Homo sapiens with 6 samples.

How the data were processed

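The series holds 6 RNA-seq libraries of HCCLM3 cells, 3 treated with CC-885 for 24 h and 3 with DMSO. Cells were grown in DMEM with serum, and total RNA was extracted with an RNeasy kit, per the labels' protocols. Libraries were made with the Hieff NGS MaxUp Dual-mode mRNA kit, per the labels' protocols, whose strand setting is not stated. The deposited table holds whole-number counts per gene with no normalization, 1 column per library, as read from its values and the file header. The aligner, the counting program and the annotation are not given in the sources used here. The submitters' processing notes list the mouse builds GRCm38 and mm10, while all 20263 row identifiers are human Ensembl genes, so no coordinates are given.

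Identifiers were paired with symbols by a table of gene names (20148) or by GENCODE 29 (76), and 39 had no name. Rows sharing a symbol (5) kept their identifier. Of all rows 3403 were at 0 in every library. Total counts per library ran from 30432509 to 39809131, and a count of 0 in a library allows 0.0754 to 0.0986 CPM (3 counts of the total). Such limits cover counting error only. Low counts were mostly even, and whether reads or fragments were counted is not given in the sources used here, so the totals may exceed the number of fragments. Where a fragment was counted more than once, a count of 0 allows more than these limits.

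The fit used edgeR 4.0.16 under R 4.3.3, with TMM factors, genes kept by filterByExpr (minimum count 10), robust quasi-likelihood dispersions and the quasi-likelihood F test of CC-885 against DMSO with no covariate. P-values were adjusted by the Benjamini-Hochberg method over the 13444 tested genes, and genes with an adjusted p below 0.05 were called. Every adjusted p of a gene is from this test unless another is named. Standard errors were taken as the absolute log2 fold change over the square root of F, an approximation. CPM, counts scaled to the library total, are TMM-normalised, and means are given with the SD of 3 libraries. On simulated counts with the real means and library sizes the fit recovered 16.4% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 93.9% of those changed 4-fold, and 5.51% of its calls were false (13322 genes). Only 67, 67 and 66 genes were changed by these folds. In the real fit 7069 genes were called, which makes the adjusted threshold less strict. The simulated shares therefore do not measure how many real changes were missed.

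The 40 gene lists, the design, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members (37) were tested with camera of limma 3.58.1 at its preset correlation of 0.01, which compares a list with the other genes, and adjusted over lists. The correlation estimated from the data and the rotation test fry were alternatives. A simulated list with changed members was called and 0 of 40 unchanged lists were. The simulated genes varied independently of each other, so this check cannot show false calls that arise from correlated members. Members were counted as higher or lower by the gene test, over all genes and over the list alone.

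The naming rule took GOLM1, CRBN, GSPT1 and the other neosubstrates with any value. It took the 12 higher and 12 lower called genes with the largest change among those with a mean CPM of at least 5 and no overlap between the groups, leaving out clone and accession names. It took up to 2 higher and 2 lower members of each list with the smallest p and members that went against their list, and the 5 most abundant genes. Genes named outside it are marked as such, apart from genes given only as absent or as called without a single library. Overlaps of named genes with another gene annotated in GENCODE 29 are given beside them, since their counts are less certain.

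The alternatives were DESeq2 size factors, library size only, the Wald test of DESeq2 1.42.0, limma-voom, no filter on low counts, a CPM of at least 5 in at least 3 libraries, the replicate number as a block, and each library left out in turn. Where a library was left out, genes were filtered anew, so a list may hold other tested members. Offsets from a spline of GC content and transcript length, and halved counts, were added after the data were seen. For lists, DESeq2 size factors, the Wald test, limma-voom and no filter were not run. The sequence reads were not used here.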

Results

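Gene expression was measured by RNA sequencing in HCCLM3 cells, a human hepatocellular carcinoma line known for its metastatic behaviour, after 24 h with CC-885 or with the solvent DMSO. CC-885 is a cereblon modulator: it binds CRBN, the substrate receptor of a CUL4 ubiquitin ligase, and directs the ligase to proteins it does not otherwise mark, of which the translation termination factor GSPT1 is the best known. The dose was not given in the sources used here. Each group held 3 libraries, and the total count per library was 30432509, 39809131 and 34948287 with CC-885 and 37574380, 34795375 and 32952518 with DMSO. The groups were well separated. The lowest correlation of log2 CPM (the count scaled to library size) within a group was 0.977 and the highest between groups was 0.946, and the first principal component held 72.8% of the variance. The labels do not say that the 3 libraries of a group came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical.

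The study asked how CC-885 acts on GOLM1, a Golgi membrane protein that its title names as ubiquitinated and degraded, and on the growth and spread of these cells. The mRNA of GOLM1 (ENSG00000135052) was not called different, at 240 ± 83.1 CPM with CC-885 and 307 ± 27.9 CPM with DMSO (mean ± SD, n = 3). Its log2 fold change was -0.36 (SE 0.25, edgeR quasi-likelihood test, adjusted p = 0.248). A single library set most of this difference. CC-885 replicate 1 gave 145 CPM and the other CC-885 libraries 274 and 300.0 CPM, and without replicate 1 the log2 fold change was -0.09 (adjusted p = 0.69). The counts speak of mRNA and not of the protein. CRBN (ENSG00000113851) stood at 22.1 ± 1.13 and 21 ± 2.2 CPM (log2 fold change 0.07, SE 0.14, adjusted p = 0.683), and overlaps TRNT1 on the opposite strand. GSPT1 (ENSG00000103342) mRNA was higher, at 347 ± 26.0 against 229 ± 20.3 CPM (log2 fold change 0.60, SE 0.14, adjusted p = 0.00334), and each CC-885 library lay above each DMSO library.

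Of 18 genes fixed in advance as CRBN neosubstrates, proteins that CRBN takes up only in the presence of such compounds, 14 were tested, 5 were higher and 0 lower. Besides GSPT1 these were ZFP91 (log2 fold change 0.90, adjusted p = 0.000234), ZNF827 (1.31, adjusted p = 0.00169), CSNK1A1 (0.47, adjusted p = 0.0124) and PATZ1 (0.46, adjusted p = 0.0239). The call of CSNK1A1 was lost without CC-885 replicate 3 (adjusted p = 0.0568), and that of PATZ1 without CC-885 replicate 1 (adjusted p = 0.0627) or replicate 2 (adjusted p = 0.0845). ZFP91 and CSNK1A1 each overlap another annotated gene on the same strand and BNIP3L, PLK1 and CDK4 on the opposite strand, so their counts are less certain. The log2 fold changes of BNIP3L (0.31), WIZ (0.40), HBS1L (0.22), ZNF692 (0.01), PLK1 (-0.13), SALL4 (-0.23), CDK4 (-0.25), IKZF2 (-0.28) and RAB28 (-0.40) did not pass the test. Without DMSO replicate 3, WIZ (0.59, adjusted p = 0.0077), CDK4 (-0.43, adjusted p = 0.0205) and RAB28 (-0.53, adjusted p = 0.0221) passed, and without DMSO replicate 2, BNIP3L (0.42, adjusted p = 0.0103) and PLK1 (-0.29, adjusted p = 0.0489). With offsets for GC content and transcript length WIZ (adjusted p = 0.014), RAB28 (0.0234) and SALL4 (0.0482) passed. As a list, the neosubstrates were not called against the other genes (camera, adjusted p = 0.355). The Golgi list, GOLM1 with Golgi matrix and golgin genes, had 10 higher and 3 lower among 19 (adjusted p = 0.161). GCC1 (log2 fold change 0.95) and GOLGA4 (0.96, with a gene on the opposite strand), golgins of the trans-Golgi, were higher, while GOLPH3L (-0.84), GOLIM4 (-0.61) and GOLGA1 (-0.35) were lower. In the list of the CUL4-CRBN ligase and its partners 5 of 13 were higher and 3 lower (adjusted p = 0.983). The largest change there was that of RBX1, the RING subunit of cullin ligases, which was lower (7.05 ± 0.255 against 26.6 ± 9.05 CPM, log2 fold change -1.91, adjusted p = 7.42e-05). The mean of this list (-0.02) had the opposite sign to its median (0.08) and its test.

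CC-885 changed a large part of the measured transcriptome in both directions. Of 13444 genes tested, 3471 (25.8%) were higher and 3598 (26.8%) lower at an adjusted p below 0.05, and 1106 were higher and 1389 lower by at least 2-fold. All changes are relative to the other genes of a library. The scaling centres them, so it partly sets the near balance of higher and lower genes. A change in the total RNA of a cell cannot be seen from these counts. With genes limited to a CPM of at least 5 in at least 3 libraries, 783 were lower by at least 2-fold.

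**Figure D1:**
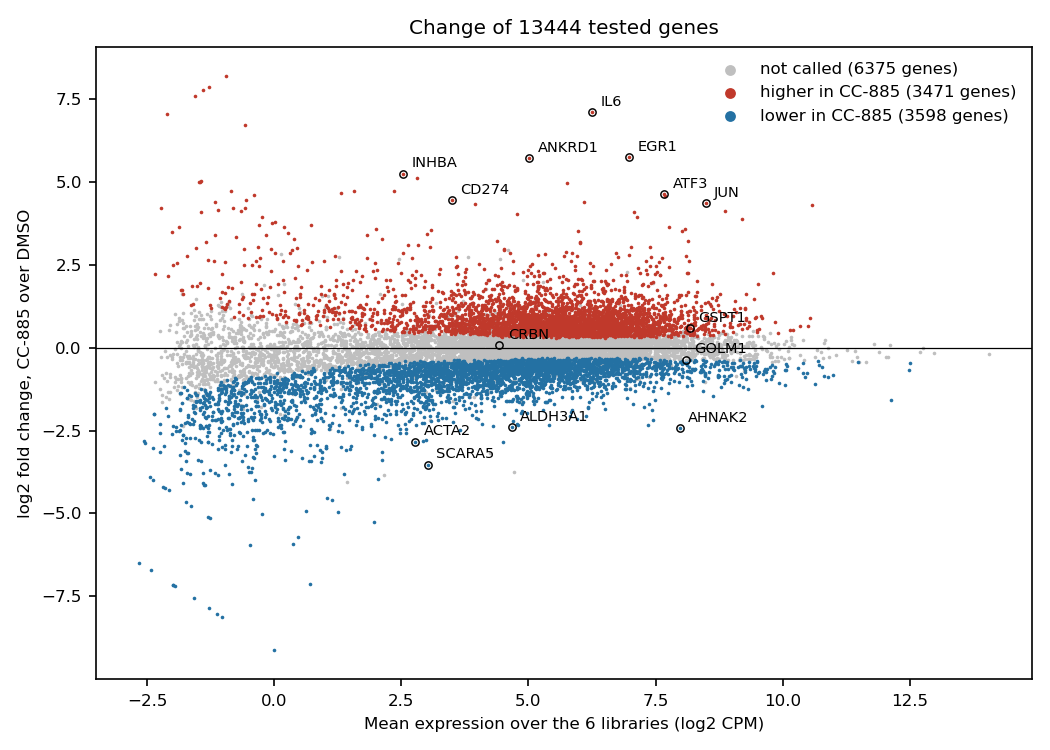
Log2 fold change of CC-885 over DMSO against the mean of the 6 libraries (log2 CPM), 1 point per tested gene, in red where higher and blue where lower at an adjusted p below 0.05 and in grey where not called. Circles mark named genes: IL6 lies at 7.09 and SCARA5 at -3.53, while GOLM1 (-0.36) and CRBN (0.07) lie in the grey band.

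Among genes with a mean CPM of at least 5, the largest increase was that of IL6. This gene, a pro-inflammatory cytokine, went from 1.11 ± 0.169 CPM with DMSO to 152 ± 14.7 CPM with CC-885 (log2 fold change 7.09, SE 0.18, adjusted p = 1.81e-09). EGR1, a serum-induced zinc finger factor, was 53.1-fold higher (log2 fold change 5.73, SE 0.28), and ANKRD1, a target of YAP, 52.1-fold (5.70, SE 0.22). INHBA, the beta A subunit of activins, reached 11.3 ± 1.45 CPM from 0.291 ± 0.118 CPM (5.24, SE 0.27). The other genes of the 12 with the largest increase were CREB5 (5.12), the hair keratin KRT34 (4.97), RBBP8NL (4.71), the stress-induced factor ATF3 (4.62), the focal adhesion scaffold NEDD9 (4.57), CD274 (4.44), the ERK phosphatase DUSP5 (4.39) and JUN (4.35), an AP-1 subunit. CD274 encodes the immune checkpoint ligand PD-L1, which stood at 21.4 ± 0.78 CPM with CC-885 and 0.988 ± 0.469 CPM with DMSO. The adjusted p of these 12 genes was 1.97e-06 or smaller. IL6 and NEDD9 overlap another gene on the opposite strand, and since the counting is not stated to use strand, reads of such a pair cannot be told apart.

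Among genes with a mean CPM of at least 5, the largest decrease was that of SCARA5. This gene, a ferritin receptor, went from 14.9 ± 2.04 to 1.29 ± 0.5 CPM (log2 fold change -3.53, SE 0.25, adjusted p = 2.29e-06). PDXP, pyridoxal phosphatase, was lower (-2.85), and overlaps another annotated gene on the same strand. ACTA2, smooth muscle actin, went from 12 ± 2.79 to 1.68 ± 0.389 CPM (-2.84, SE 0.24, adjusted p = 5.28e-06). The other 9 were FOXN1 (-2.81), WFIKKN1 (-2.80), GVQW3 (-2.59), TMEM80 (-2.57), FGFBP1 (-2.49), the taste receptor subunit TAS1R3 (-2.47), SECTM1 (-2.45), AHNAK2 (-2.43) and ALDH3A1 (-2.41), an aldehyde dehydrogenase. AHNAK2 was the most abundant of them, at 424 ± 69.8 CPM with DMSO and 78.7 ± 14 CPM with CC-885. SCARA5, ACTA2, GVQW3, TMEM80, TAS1R3, AHNAK2, ALDH3A1 and GAPDH overlap a gene on the opposite strand, and MT-CO3 and MT-ND4 a gene on the same strand. Of the 5 most abundant genes, the mitochondrial MT-CO1, MT-CO3, MT-ND4 and MT-CO2 had log2 fold changes of -0.18, -0.15, -0.02 and -0.14 and were not called. The glycolytic enzyme GAPDH, a gene with many processed pseudogenes, was lower (-0.47, SE 0.17, adjusted p = 0.0354), a call lost without CC-885 replicate 1 (adjusted p = 0.126), CC-885 replicate 2 (0.128), CC-885 replicate 3 (0.127) or DMSO replicate 1 (0.116), with no filter on low counts (0.057) and with offsets for GC content and transcript length (0.066).

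**Figure D2:**
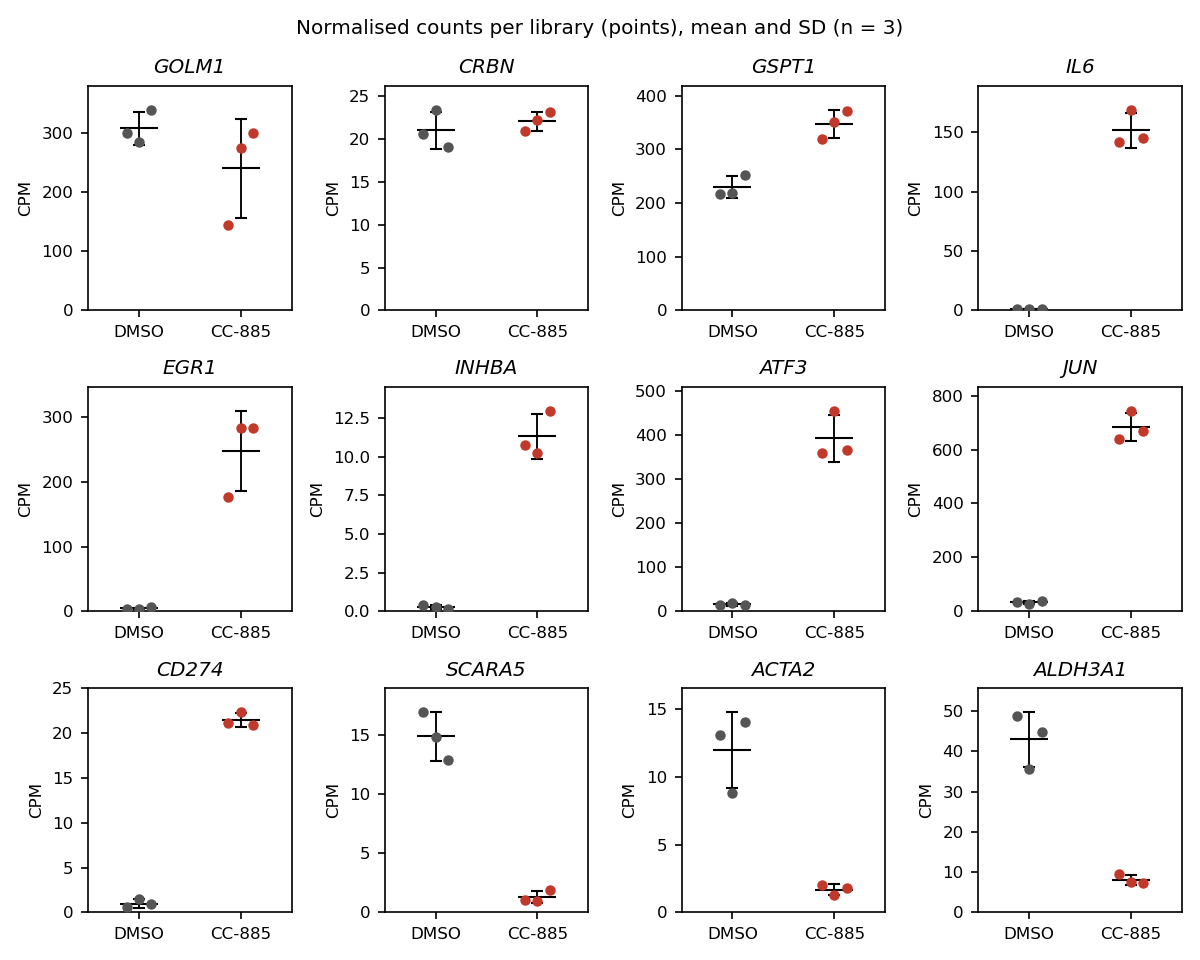
Normalised counts (CPM, linear axes from 0) of 12 named genes in each library, with the mean and SD of 3 libraries per group as bars. GSPT1 and the induced genes lie higher in each CC-885 library, and GOLM1 shows 1 CC-885 library at 145 CPM below the others.

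Immediate early genes, the transcripts switched on by growth factor and stress signalling, rose as a group: 21 of 22 tested were higher and 0 lower, with a median log2 fold change of 2.63 (camera with its preset correlation, adjusted p = 1.63e-34; adjusted p = 0.0792 with an estimated correlation). DUSP1 went from 51.4 ± 2.88 to 889 ± 86.0 CPM (log2 fold change 4.11) and DUSP5 from 6.24 ± 1.02 to 131 ± 16.1 CPM (4.39), and both encode phosphatases of MAP kinases. Targets of NF-kB rose as well, with 15 of 17 higher and a median of 2.62 (adjusted p = 5.11e-26; adjusted p = 0.0792 with an estimated correlation). After IL6 the smallest p there was that of TRAF1, an adaptor of TNF receptors (29.5 ± 2.73 against 1.47 ± 0.353 CPM, log2 fold change 4.33). The chemokine gene CCL2 went the other way, at 0.948 ± 0.217 against 1.7 ± 0.0343 CPM (-0.85, adjusted p = 0.0217), and its call was lost without CC-885 replicate 2 (adjusted p = 0.0863), CC-885 replicate 3 (0.0733) or DMSO replicate 1 (0.0653), and with the DESeq2 test (0.0536) or GC and length offsets (0.0815). Of 17 targets of TGF-beta and YAP, 12 were higher and 1 lower (median 1.17, adjusted p = 2.77e-15; adjusted p = 0.0792 with an estimated correlation). ANKRD1 and the cytokine TGFB2 (log2 fold change 3.51, 116 ± 8.8 against 10.2 ± 1.52 CPM) had the smallest p of this list, TGFB2 with an annotated transcript of another gene on its strand, and ID1, an inhibitor of differentiation factors, was the lower member (-0.66, adjusted p = 0.00178).

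The integrated stress response, the program that ATF4 drives when translation initiation factor eIF2 is phosphorylated, rose with 28 of 34 genes higher (median log2 fold change 0.98, adjusted p = 6.17e-13; adjusted p = 0.0792 with an estimated correlation). ATF3 went from 15.9 ± 2.83 to 393 ± 53.4 CPM (log2 fold change 4.62). PPP1R15A, the phosphatase subunit that reverses eIF2 phosphorylation, went from 41.6 ± 9.96 to 475 ± 50.4 CPM (3.51). ATF4 itself (1.39, adjusted p = 1.62e-05), asparagine synthetase ASNS (1.02, adjusted p = 0.000112) and DDIT3, which encodes CHOP (1.5, adjusted p = 8.17e-05), were higher too, and are named here after their values were seen. ASNS and DDIT3 overlap another gene on the same strand, and DDIT3 also the methionyl-tRNA synthetase gene on the opposite strand. The mTORC1 inhibitor gene DDIT4 went against its list (-0.71, adjusted p = 0.0032). Aminoacyl-tRNA synthetases, many of them ATF4 targets, were called higher as a list with 10 of 20 higher (median 0.43, adjusted p = 0.0381; adjusted p = 0.265 with an estimated correlation), with the smallest p for GARS1 (1.26) and CARS1 (1.19), which, like DDIT4, overlap genes on the opposite strand. QARS1 was lower (-0.43, adjusted p = 0.0207), a call lost without CC-885 replicate 1 (adjusted p = 0.0607), CC-885 replicate 2 (0.0583), CC-885 replicate 3 (0.0813) or DMSO replicate 1 (0.107). The call of this list was lost with the CPM filter of 5 (adjusted p = 0.108) and with offsets for GC content and length (0.0523). In the list of serine, one-carbon and proline synthesis 6 of 14 genes were higher and 2 lower (adjusted p = 0.305).

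Genes of the unfolded protein response in the endoplasmic reticulum did not follow. Among 24 chaperone and degradation genes 4 were higher and 11 lower, and the list was not called (median -0.30, adjusted p = 0.305). CRELD2 (-0.92) and the disulfide isomerase PDIA4 (-0.78) were lower. Higher were the transcription factor XBP1 (log2 fold change 1.49, 201 ± 42.3 against 71.8 ± 7.35 CPM), SELENOS (0.81), DNAJB9 (0.47, with THAP5 on the opposite strand) and HERPUD1 (0.48). In the cytosolic heat shock list 5 of 15 were higher and 4 lower (adjusted p = 0.942), with the constitutive chaperone HSPA8 lower (-0.89, 1332 against 2473 CPM) and DNAJB4 higher (0.73).

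Transcripts around translation moved in different directions. Ribosomal protein mRNAs fell: 62 of 75 were lower and 0 higher, with a median log2 fold change of -0.70 (adjusted p = 6.76e-09; adjusted p = 0.615 with an estimated correlation). They took 4.38, 4.55 and 4.0% of all counts in the CC-885 libraries and 7.06, 8.92 and 5.56% in the DMSO libraries, so the spread among DMSO libraries was wide but did not reach the CC-885 values. RPL3 went from 2178 ± 358 to 1024 ± 158 CPM (-1.09) and RPS27 from 1322 ± 324 to 625 ± 66.6 CPM (-1.08). Ribosome biogenesis factors were called higher, with 19 of 29 higher (median 0.42, adjusted p = 0.0139; adjusted p = 0.347 with an estimated correlation). BYSL (1.15), a factor of the small subunit, and RRN3 (1.21), an initiation factor of RNA polymerase I, had the smallest p, while NHP2, a protein of small nucleolar ribonucleoproteins that overlaps RMND5B on the opposite strand, was lower (-0.70). This call was lost with the CPM filter of 5 (adjusted p = 0.0594). Of 15 genes of translation termination and ribosome rescue, 6 were higher and 0 lower (adjusted p = 0.194). Among them were LTN1 (log2 fold change 1.19), the ubiquitin ligase for stalled nascent chains, and the rescue factor PELO (1.07), which overlaps ITGA1 on the same strand.

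Factors of nonsense-mediated decay, which removes mRNAs with early stop codons, rose with 11 of 15 higher and 0 lower (median 0.51, adjusted p = 0.00555; adjusted p = 0.265 with an estimated correlation). UPF3B (1.26) and SMG9 (1.21) had the smallest p. RNAs that this pathway degrades were also called higher, with 5 of 6 tested (median 0.99, adjusted p = 4.2e-06; adjusted p = 0.0792 with an estimated correlation). Only 6 of the 19 genes fixed for that list have a row in the count table. The smallest p there were those of GADD45A (log2 fold change 3.04, 232 ± 9.88 against 28.1 ± 0.974 CPM) and GADD45B (2.79, 63.3 ± 6.52 against 9.17 ± 1.27 CPM), which are also growth arrest genes induced by stress.

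Genes of DNA replication and the G1/S transition were called higher, with 18 of 30 higher and 2 lower (median 0.48, adjusted p = 0.00123; adjusted p = 0.347 with an estimated correlation). CDC6, a licensing factor of replication origins, went from 123 ± 7.98 to 373 ± 29.1 CPM (log2 fold change 1.6), and E2F2 from 40 ± 3.65 to 106 ± 6.13 CPM (1.41). DSCC1, a subunit of a clamp loader at replication forks, was lower (-0.36, adjusted p = 0.0485). The call of DSCC1 was lost when any library was left out (adjusted p between 0.0584 and 0.146), with DESeq2's size factors (0.0569) or its Wald test (0.0705), and with no filter on low counts (0.0763). Mitotic genes showed no common direction, with 4 of 30 higher and 4 lower (adjusted p = 0.983), KIF23 (0.74) and NDC80 (0.76) among the higher and KIF20A (-0.70) and PTTG1 (-0.63) among the lower. KIF23 and KIF20A overlap genes on the opposite strand. Replication-dependent histones had 4 of 17 higher and 5 lower (adjusted p = 0.983). The mean and median of the mitotic list were 0.00 and 0.04 while its test leaned lower, and the histone list had a mean of 0.04 with a median of -0.22.

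Interferon-stimulated genes fell, with 11 of 21 lower and 0 higher (median -0.67, adjusted p = 0.00555; adjusted p = 0.149 with an estimated correlation). The antiviral genes IFIT1 (3.54 ± 0.375 against 12.4 ± 2.07 CPM, log2 fold change -1.81) and OAS1 (16.8 ± 1.08 against 35.5 ± 1.59 CPM, -1.08) had the smallest p. IFI27 had 0 counts in the 3 CC-885 libraries and a mean of 0.515 CPM with DMSO. If each fragment was counted once, this makes it at least 5.83-fold lower against a floor of 3 counts per library. The transcription factor gene IRF7 was not called (0.35, adjusted p = 0.0686) but passed as higher without CC-885 replicate 3 (0.46, adjusted p = 0.037) and with GC and length offsets (0.66, adjusted p = 0.00125). With IFI27 at that bound the list's median was -0.67 too. Targets of p53 had 11 of 21 lower and 3 higher, and the list did not pass the test (median -0.61, adjusted p = 0.0651; adjusted p = 0.462 with an estimated correlation). It passed under other settings, among them without CC-885 replicate 3 (adjusted p = 0.0464), without DMSO replicate 3 (0.0173), with the CPM filter of 5 (0.0305) and with halved counts (0.0468). ZMAT3 (-1.93) and FDXR (-1.89) were lower, and GADD45A (3.04), POLK (1.25) and AEN (0.53) higher. OAS1 and POLK overlap genes on the opposite strand. In the BCL2 family 6 of 15 were higher and 3 lower (adjusted p = 0.573), with the pro-apoptotic PMAIP1 higher (1.6) and BAX lower (-0.79). The mean of that list (-0.12) had the opposite sign to its median (0.28).

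**Figure D3:**
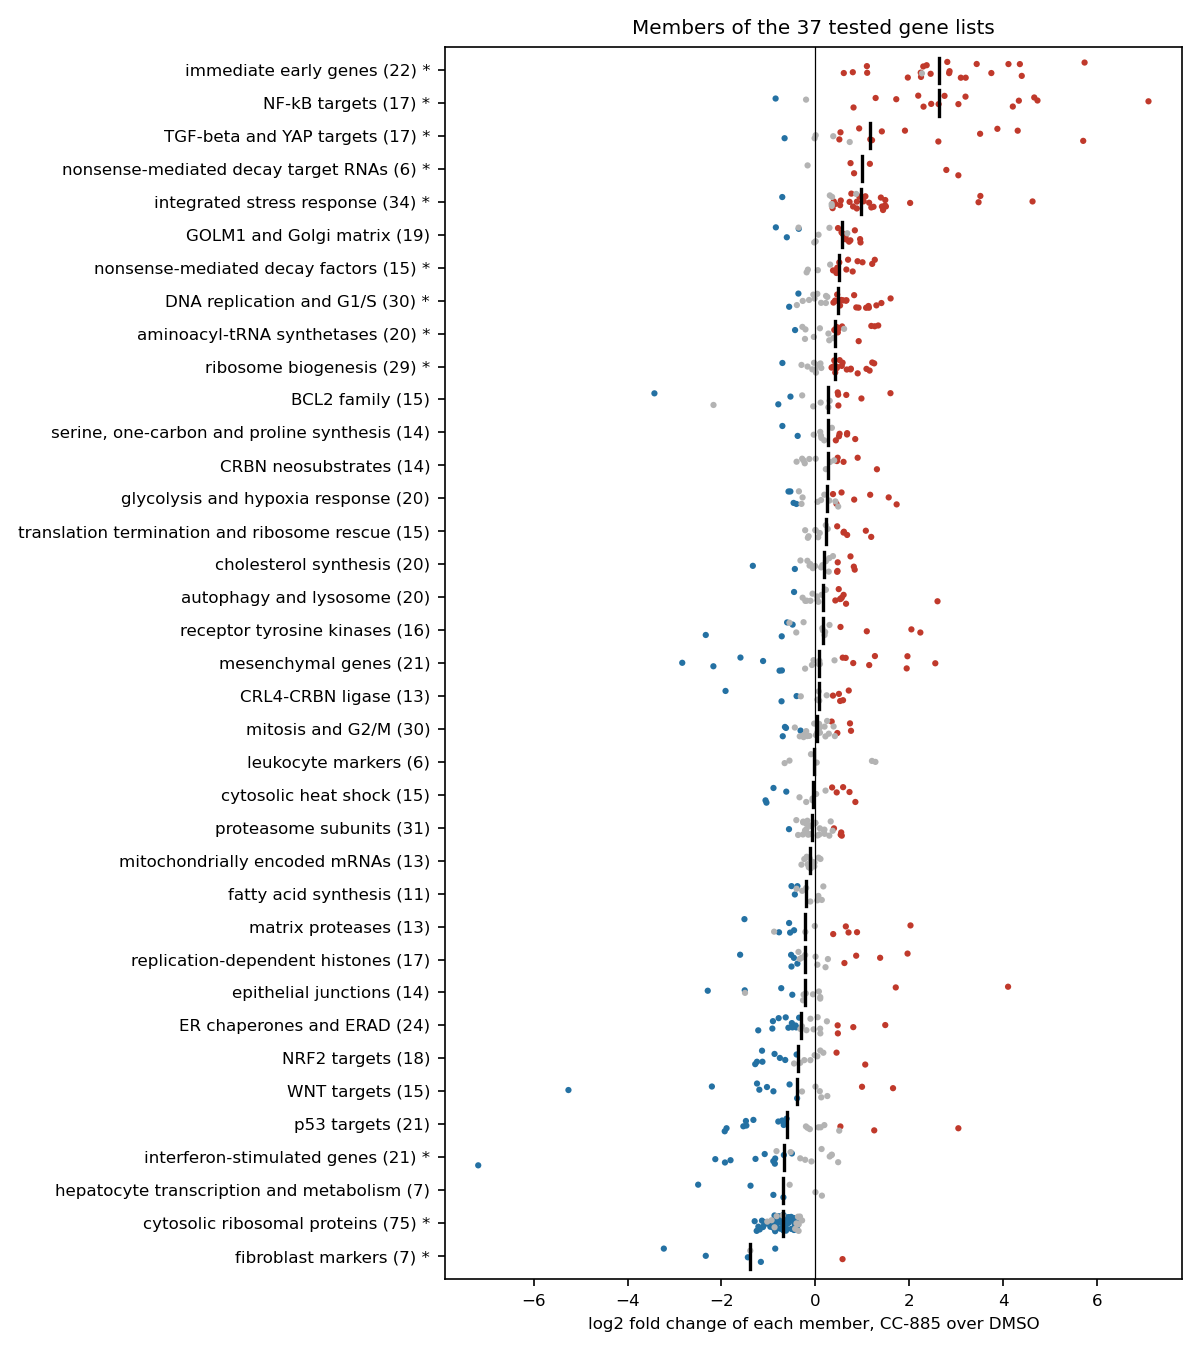
Log2 fold change of each tested member of the 37 gene lists with at least 5 tested members, 1 point per gene (red higher, blue lower, grey not called), with the list median as a black bar and the number of tested members in brackets. A star marks the 12 lists called by camera with the preset correlation, from immediate early genes (median 2.63) to fibroblast markers (-1.39).

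For lists tied to spread and invasion, members changed strongly in both directions and no list was called. Of 14 tested junction genes of epithelia 2 were higher and 4 lower (adjusted p = 0.983). The tight junction genes CLDN1 (log2 fold change 4.10, 256 ± 9.13 against 14.9 ± 3.38 CPM) and TJP1 (1.71) were higher, and the membrane protease ST14 (-2.29) and CLDN7 (-1.51) lower. Of 21 mesenchymal genes 8 were higher and 6 lower (adjusted p = 0.721), with TAGLN (1.96) and ZEB2 (1.94), a repressor of E-cadherin, higher and ACTA2 (-2.84) and S100A4 (-2.17) lower. Matrix proteases and their inhibitors had 5 of 13 higher, among them MMP9 (2.02) and the urokinase receptor PLAUR (0.89), and 5 lower, among them urokinase itself, PLAU (-1.51), and TIMP3 (-0.78; list adjusted p = 0.983). Receptor tyrosine kinases had 4 of 16 higher and 4 lower (adjusted p = 0.912), with EPHA2 (2.23) and DDR2 (2.04) higher and PDGFRB (-2.33) and DDR1 (-0.72) lower. CLDN7, TAGLN, ACTA2, ZEB2, MMP9 and PLAU overlap genes on the opposite strand, and CLDN7 also a gene on the same strand. The median and mean of the junction list (-0.23 and -0.08) and of the protease list (-0.21 and -0.02) were below 0 while the tests leaned higher.

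Lists of metabolism and protein turnover were not called. The counts of higher and lower members were 6 and 2 of 20 for cholesterol synthesis (adjusted p = 0.594), 0 and 3 of 11 for fatty acid synthesis (0.588), 7 and 4 of 20 for glycolysis and the hypoxia response (0.305), 2 and 8 of 18 for NRF2 targets (0.102), 4 and 1 of 31 for proteasome subunits (0.983), 8 and 1 of 20 for autophagy and lysosome (0.265) and 2 and 8 of 15 for WNT targets (0.141). The autophagy gene GABARAPL1 was 6.06-fold higher (log2 fold change 2.60, 488 ± 60.8 against 80.4 ± 27.5 CPM), and the glutamate transporter SLC1A2 of the WNT list was lower (-5.26, 0.194 ± 0.0175 against 7.57 ± 2.89 CPM), and both overlap a gene on the opposite strand. The hypoxia-induced peptide gene ADM (1.73) was higher and the transporter ABCC2 of the NRF2 list lower (-1.24). For proteasome subunits the median (-0.08) had the opposite sign to the mean (0.01) and the test.

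Few genes that mark differentiated liver were measurable. The name HCCLM3 is that of the labels, and the identity of the cells was not tested here. Of 24 secreted liver protein genes 22 stood below 1 CPM, and 11, among them ALB, AFP, APOB and TTR, had 0 counts in all 6 libraries, which allows up to 0.0143 CPM over the counts of all 6 (3 counts of the total). This limit covers counting error only. It also takes each fragment as counted once, which the mostly even low counts put in doubt. Complement C3 (114 ± 6.97 against 92.7 ± 35.5 CPM, log2 fold change 0.29, adjusted p = 0.387) was the only gene of them above 10 CPM. Of the 4 tested 0 were called by edgeR, 0 at an unadjusted p below 0.05 and 0 by DESeq2 or limma-voom, and C3 passed without DMSO replicate 3 (0.58, adjusted p = 0.0288). Of 24 hepatocyte transcription factors and enzymes 19 stood below 1 CPM, 7 were tested, and 4 were lower (list median -0.68, adjusted p = 0.0669; adjusted p = 0.34 with an estimated correlation). These were the urea cycle genes CPS1 (966 ± 49.3 against 1797 ± 107 CPM, log2 fold change -0.90) and ASS1 (4394 ± 311 against 7049 ± 908 CPM, -0.68), and the transcription factors CEBPA (-1.38) and HNF4A (-2.50, 0.213 ± 0.184 against 1.25 ± 0.184 CPM), ASS1 and HNF4A being named after their values were seen. CEBPA overlaps genes on the opposite strand. The list passed the test without CC-885 replicate 1 (adjusted p = 0.0172), 2 (0.0177) or 3 (0.0318) and without DMSO replicate 1 (0.0371) or 2 (0.0172), but not without DMSO replicate 3 (0.088). Genes were filtered anew in these runs, with 13560 to 13688 tested against 13444, so members with few counts may have entered. The list median ran from -0.92 to -0.65 in them. These passes therefore do not show that the same members hold the result.

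Markers of other cells were examined because they could reveal foreign RNA. Fibroblast markers were called lower, with 5 of 7 lower and 1 higher (median -1.39, adjusted p = 0.00555; adjusted p = 0.347 with an estimated correlation). PDGFRB (14.1 ± 0.37 against 70.9 ± 10.7 CPM) and DCN (0.127 ± 0.00902 against 1.21 ± 0.308 CPM) were lower and COL1A1 was higher (155 ± 16.3 against 104 ± 6.22 CPM). Other fibroblast markers were absent or nearly so and not tested. LUM had 0 counts, and COL1A2, POSTN, FAP and COL6A3, named after their values were seen, had 2, 2, 7 and 8 counts over all 6 libraries. Whether the lower markers reflect foreign RNA was not tested. Of 14 markers of leukocytes and other blood cells, among them the haemoglobin genes HBA1 and HBB of red cells, 6 were tested and 0 called by edgeR (3 at an unadjusted p below 0.05, 0 by DESeq2, 1 by limma-voom, list adjusted p = 0.983), and PTPRC, CD3E and LYZ had 0 counts. Without CC-885 replicate 2, ITGAM was called higher (log2 fold change 1.67, adjusted p = 0.0152). Without DMSO replicate 2, HBB was called higher (1.78, adjusted p = 0.0229) and HBA1 lower (-0.73, adjusted p = 0.048). HBB also passed with limma-voom (adjusted p = 0.038), with GC and length offsets (0.0174) and with halved counts (0.0402). Their median (-0.03) and mean (0.20) differed in sign. Of 10 endothelial markers 4 were tested, too few for the list test, of which 3 were higher and 1 lower, while TIE1 and EMCN had 0 counts. CDH5 (2.11 ± 0.366 against 0.168 ± 0.0143 CPM), ESAM (134 ± 55.9 against 39.5 ± 8.16 CPM) and, named after its values were seen, VWF (1.88 ± 0.655 against 0.929 ± 0.258 CPM) were higher, and ERG was lower (2.86 ± 0.536 against 4.38 ± 1.16 CPM, adjusted p = 0.0478). The call of ESAM was lost without DMSO replicate 3 (adjusted p = 0.0768). That of ERG was lost without CC-885 replicate 1 (adjusted p = 0.149), CC-885 replicate 2 (0.11), DMSO replicate 1 (0.0781) or DMSO replicate 3 (0.195), and with DESeq2's size factors (0.0539), its Wald test (0.0678) or limma-voom (0.0621). The 13 mitochondrially encoded mRNAs had 0 calls by edgeR, 0 at an unadjusted p below 0.05 and 0 by DESeq2 or limma-voom (list adjusted p = 0.912), and up to 3 calls without a single library. Without DMSO replicate 3, MT-ND1 (0.48, adjusted p = 0.0487) and MT-ATP8 (0.57, adjusted p = 0.00836) were called higher, MT-ATP8 overlapping MT-ATP6 on the same strand, and without DMSO replicate 2, MT-ND3 (-0.33, adjusted p = 0.0457) and MT-ND5 (-0.52, adjusted p = 0.0168) were called lower. They took 5.3, 4.83 and 6.16% of counts with CC-885 and 5.96, 4.29 and 8.16% with DMSO. No member of the list of small non-coding RNAs has a row in the table.

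Across the 40 fixed lists 37 were tested, 9 were called higher and 3 lower with the preset correlation, and 0 with an estimated correlation, under which 6 had an unadjusted p below 0.05. The rotation test fry, which asks whether the members of a list move on balance in a common direction, called 24. Adjusted over the list alone, the counts of higher and lower members were as over all genes, except for ribosomal proteins (70 lower), TGF-beta and YAP targets (14 higher), mesenchymal genes (9 higher), NRF2 targets (9 lower), histones (6 lower), mitotic genes (3 higher and 3 lower), proteasome subunits (3 higher and 0 lower) and fatty acid synthesis (0 lower).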

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

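The offsets for GC content and transcript length and the halved counts were chosen after the data were seen. The counts of higher and lower genes stayed within 1.5 times their values in every alternative run, with 1 exception. With a CPM of at least 5 in at least 3 libraries 783 genes were lower by at least 2-fold against 1389, where 10924 genes were tested in place of 13444. Across single libraries left out, 2897 to 3650 genes were higher and 2908 to 3720 lower, and of the 7069 calls 5678 (without DMSO replicate 1) to 6575 (without DMSO replicate 3) kept their direction and call. With the GC and length offsets 6364 of 7063 did and 1 was called in the opposite direction. The share of higher genes among the calls was 49.1%, and 44.4% with library size only. The log2 fold change of GOLM1 ran from -0.55 to -0.09 with a library left out and was not called in any alternative run. Camera called 0 lists with an estimated correlation and fry called 24, against 12, where fry does not compare a list with other genes. The other alternatives called 10 to 14 lists. The 10 came with the CPM filter of 5, where 34 lists were tested in place of 37, and fibroblast markers were not among them. Named genes kept direction and side of the threshold in 2560 of 2675 comparisons, lost the call in 85, gained it in 30 and reversed in 0. For lists these numbers were 441 of 478, 15, 22 and 0. The cause of these losses and gains was not tested. With the replicate number as a block 3597 genes were higher and 3676 lower, 1126 and 1346 of them by at least 2-fold, GOLM1 stood at -0.42 (adjusted p = 0.112), and 13 lists were called, p53 targets being the added list (adjusted p = 0.043). Of the named genes DSCC1 lost its call under the block (-0.36, adjusted p = 0.0541), and HBB (1.30, adjusted p = 0.0488) and IRF7 (0.35, adjusted p = 0.0458) gained one. The numbers are not stated to pair the samples, and deviations of libraries with equal numbers correlated at 0.096, 0.031 and 0.072. CC-885 replicate 2 correlated best with DMSO replicate 1 (0.037). With halved counts 6827 of the 6874 calls tested kept their direction and call. A simulated 1.5-fold change was called in 16.4% of genes, but few genes were changed in that simulation. Real changes of this size may be called more often.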

Other observations

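The gene families in this paragraph were chosen after their values were seen, so the comparison with random lists that was run restates that choice, and only their numbers are given, as a description. The tests of read pairs and of members without UAUUUAU in the paragraphs after it were also chosen after the result was seen. Genes whose symbol starts with ZNF, mostly zinc finger transcription factors, had 171 of 414 tested higher and 54 lower, with a median log2 fold change of 0.40. The deubiquitinases with a USP symbol had 25 of 47 higher and 1 lower (median 0.47), and the KLF transcription factors 10 of 15 higher and 1 lower (median 0.72). Genes with an NDUF symbol, mostly subunits or assembly factors of respiratory complex I, had 27 of 48 lower and 2 higher (median -0.44). Cytochrome c oxidase genes (COX) had 4 of 12 lower and 0 higher (median -0.59). With library size only, with DESeq2 size factors and with each library left out the medians kept their sign, at 0.35 to 0.44 (ZNF), 0.41 to 0.48 (USP), 0.60 to 0.80 (KLF), -0.59 to -0.32 (NDUF) and -0.76 to -0.37 (COX). GC content and length were not examined for these families.

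The 56 tested members of the immediate early, NF-kB and TGF-beta and YAP lists had a median log2 fold change of 2.34. With offsets for GC content and transcript length it was 2.39 (bootstrap 2.02 to 2.91), which argues against such a bias as the cause. Many such mRNAs are short-lived through AU-rich elements, and over all genes those with UAUUUAU in the 3' UTR lay 0.151 higher than matched genes without it (permutation p = 0.001, the smallest 1000 permutations can give), above each of 20 rearranged motifs (highest 0.123). Slower decay of such mRNAs may add to the rise, but the difference of 0.151 is small beside the median of 2.34. The 35 members with the motif had a median of 2.45 and the 21 without it 2.269 (1.282 to 3.097), so the rise was not confined to members with this motif. Whether those 21 hold other AU-rich elements was not examined. Induced transcription was not tested and stays open.

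The fall of ribosomal protein mRNAs (median -0.697) lay below all of 10000 random lists matched on length, GC content and expression. Of these lists 95% lay at -0.36 to -0.158, so in this comparison those properties do not account for all of it. The members of a random list were drawn independently, so this range leaves out variation that ribosomal protein mRNAs share between libraries. With a library left out their median ran from -0.849 to -0.508, and the random lists were not redrawn for these runs. The median was -0.684 with DESeq2 size factors and -0.767 with library size only. TMM factors ran only from 0.967 to 1.055, so these scalings could hardly differ. The comparison therefore cannot decide on scaling as a cause. Part of the fall goes with length and GC content, since the offsets for these moved the ribosomal protein median to -0.47. The matched lists had a median of -0.291, but they were matched on expression too, and its share in that value was not separated. These mRNAs start with a 5' terminal oligopyrimidine tract, and 30 other mRNAs of this kind, EEF1A1 (-1.59) and EEF2 (-0.29, not called) being left out because their values had been seen, had a median of -0.251, where 95% of matched random lists gave -0.18 to 0.269. Of the 30, 3 were higher and 8 lower, where 25.8% of all tested genes were higher and 26.8% lower. The calls thus show no excess of lower genes, and only the median lay outside the random range. These random lists were drawn gene by gene too. That the fall is part of a wider loss of such mRNAs therefore stays a hypothesis.

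Among counts of 1 or 2, the lowest share of 2 in a library was 78.4% and the highest 83.3%. Among counts of 21 to 1000 the share of even counts was 47.8 to 50.6%, which argues against both reads of every pair having been counted. How many pairs were counted through both reads stays open.

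The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3471 higher and 3598 lower genes, 1106 and 1389 by at least 2-fold, and the highest of the other splits gave 0 for each, so that 1 split of 10 reached each real count. Every other split puts libraries of both treatments in each group, so the treatment difference widens the spread within groups. Low gene counts there were thus set by the design, and the other splits are no reference for chance. The real split called 12 lists and the highest of the others 12, so that 2 of 10 reached that number, and the lowest of the others called 5. Ribosomal proteins had a smaller p in 4 of the other splits and immediate early genes, NF-kB targets, TGF-beta and YAP targets and the integrated stress response in 0. Of the other called lists, ribosome biogenesis had a smaller p in 2 of the other splits, and fibroblast markers, interferon-stimulated genes and nonsense-mediated decay factors in 1 each. The other 9 splits still called immediate early genes in 9, the integrated stress response in 9, NF-kB targets in 8, TGF-beta and YAP targets in 7 and ribosomal proteins in 6. These splits keep part of the contrast between treatments, so such calls do not measure chance either. This contrast does not account for all calls in the other splits. Mitochondrially encoded mRNAs were called in 6 of them and proteasome subunits in 3, and the real split called neither list. Camera with the preset correlation thus called lists here that showed no called treatment difference. For ribosomal proteins, the smaller p in 4 other splits argues against the kept contrast as the only source of those calls.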
